A study of Penaeus monodon with 16 samples.

How the data were processed

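Total RNA from gills of Penaeus monodon was measured on 16 arrays of a custom Agilent design with 60-base probes, in 1 colour. The groups were taken from the sample titles: 4 control arrays and 3 arrays each at 6 h, 24 h and 48 h after WSSV infection and at the moribund stage. Per the labels' protocols, RNA was reverse transcribed from an oligo-dT primer and transcribed into Cy3-labelled cRNA. Per the file headers, the scanner images were processed with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09. The column used here, gProcessedSignal, holds an intensity per spot, background-subtracted and detrended within the array by that software, per the file headers. A table deposited by the authors holds 1 value per probe and array on the log2 scale. Set against the log2 scanner signal, its columns correlated at 0.992 to 0.998. Their 75th percentiles lay between -0.0114 and -0.0035 and their medians between -4.51 and -2.18, so its scale, centring and direction were found from the values, and the software that made it stays unknown.

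Each array had 61657 spots of 27556 probes: 12241 probes had 1 spot, 11844 had 3 and 3471 had 4. Control spots and spots with an outlier flag (843 to 1108 per array) were left out, the other spots of a probe were averaged, and no probe was saturated. Log2 values minus the array's 75th percentile were tested. Probes well above background on at least 3 of the 16 arrays were kept (15692), and 11864 were left out. Of the kept probes, 6373 were well above background on all arrays. Target names and descriptions came from the array files, where 6256 probes had a text and 4471 an informative name, and some texts are truncated. None of the target names matched the reference gene table supplied (assembly NSTDA_Pmon_1): 0 names matched. A gene is a target sequence, represented by its probe with the highest mean signal (13221 targets).

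Group means were fitted over all 16 arrays with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment per comparison and calls at an adjusted p below 0.05. Each infected group was compared with control and with the preceding infected group. Named targets were fixed by rule: per comparison with control the 6 highest and 6 lowest, and between infected groups the 3 highest and 3 lowest, among informative descriptions past the threshold with an absolute log2 fold change of at least 1 and no overlap between the arrays of the 2 groups, with 1 target per description. Where fewer than 3 passed, those with the smallest p are named. The rule adds up to 3 members per gene list and the WSSV target.

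Of 31 gene lists defined by text patterns on descriptions, 29 with at least 3 targets were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The patterns were written before the data were examined, as were the design, the rule for named targets and the first set of alternatives. They were then corrected on the description texts alone, for spelling and spacing, before any gene was tested. Muscle and hepatopancreas lists are markers of other tissues. A list's level per array is the mean over members of the log2 value minus the control mean, tested by an exact two-sided permutation test over 35 splits. Its smallest p is 0.0286, so after adjustment over 29 lists none passes unless 17 reach it, and it is not set against the camera calls.

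Targets were sorted by the end from which the clone was read (4747 kept probes from 3' reads, 7456 from 5' reads, 3489 other). A probe was placed on the same or the opposite strand where 20 bases matched, directly or as reverse complement, a probe of a target described with a coding sequence (376 probes) or, where none matched, a probe of a 5' read. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

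The steps were tested on simulated data with the real group sizes and spread, in 15589 probes of which 50 per size were shifted. Of probes shifted by 1, 2, 4 and 6 on the log2 scale, 0% to 2%, 2% to 12%, 48% to 72% and 78% to 92% were recovered over the 7 comparisons, with 48% for a shift of 4 at 24 h and in 48 h vs 24 h. Unchanged probes made up 1.54% to 8.89% of the calls, the most in moribund vs 48 h, and exceeded 5% in 4 of the 7 comparisons. Camera called 0 of the 29 lists that were not shifted in each comparison. The simulated probes varied independently of each other, without the correlation between real probes. The shares of false calls and the list result therefore need not hold for the real arrays.

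The alternatives tried were quantile normalization, the array median as the scale, normexp background correction with an offset of 50, no filter and a stricter filter on dim probes, slide as a block, arrays of the same slide alone, the replicate number as a block, only the 2 groups compared, eBayes with trend and robust options, a minimum log2 fold change of 1, the deposited log2 values, each array left out in turn, other list tests, and all probes of a target averaged. Alternatives chosen after seeing the data were a percentile over probes detected on all arrays, a common floor, scan session as a block, session 1 alone, scaling within each read end, the strand index as a covariate, no targets of 3' reads, 1 value per description in the list test, and no control 3 and 6 h 2 together.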

Results

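Gills of the black tiger shrimp Penaeus monodon were compared between control animals and animals infected with white spot syndrome virus (WSSV), a DNA virus of crustaceans. The 16 arrays comprised 4 of control gills and 3 each of gills at 6 h, 24 h and 48 h after infection and at the moribund stage. Each array carried 27556 probes for 23458 target sequences, of which 3189 targets had an informative name. Between 33.7% and 54.0% of the probes were well above background on an array, and 15692 probes entered the tests. The 75th percentile of the log2 signal ranged from 4.71 to 8.75 between arrays and was 7.95, 8.75 and 8.40 on the moribund arrays. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.788 against control and 0.842 between infected groups. Arrays are named by group and replicate, such as control 3. The labels do not state whether replicates are separate animals, so the p-values measure the spread between these arrays, part of which can be technical.

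The moribund arrays, the 48 h arrays and control 1 and 2 lay on the same slide, and the 6 h arrays, the 24 h arrays and control 3 and 4 on another. All 12 infected arrays and control 3 were scanned in the same session, and control 1, 2 and 4 in another, so a comparison within the first session has 1 control array. The session term of the scan block was estimated from the control arrays alone, so the block also compared each infected group with control 3 alone. Likewise the slide term came from the control arrays alone, as each infected group lay on 1 slide, so the slide block and the comparison within the slide both compared an infected group with the 2 controls of its slide. In each case the block and the comparison within differ in the arrays behind the spread and are not separate checks. RNA quality values were not in the files. A sequence match placed 854 probes of targets cloned as 3' reads on the strand opposite to coding sequences or 5' reads, and 217 on the same strand. Most placements rest on 5' reads: over all probes of the array, 168 of 3' reads lay opposite to a coding sequence and 12 on its strand. For 5' reads these were 25 and 42, so the 5' reads are a reference of mixed strand. A strand index was computed per array as the mean of the 854 opposite-strand probes minus the mean of the 217 same-strand probes. The opposite-strand probes were dimmer on every array, with group means of -2.81 to -0.21 against 1.64 to 2.88. The index therefore also sets dim against bright probes. The index was -4.05 ± 0.64 (SD, n = 4) in control gills, -3.07 ± 0.94 (n = 3) at 6 h, -3.08 ± 0.18 (n = 3) at 24 h, -3.02 ± 0.79 (n = 3) at 48 h and -4.45 ± 0.12 (n = 3) at the moribund stage. Its value was -3.11 on control 3, -4.13 on 6 h 2 and -3.80 on 48 h 2.

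**Figure D1:**
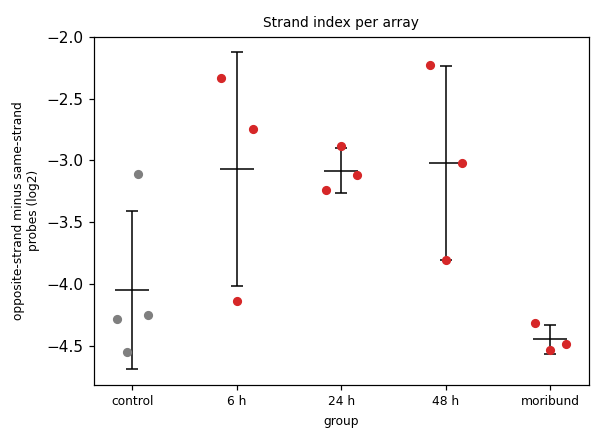
Strand index per array (vertical axis, log2 units) in the 5 groups (horizontal axis); points are arrays, and bars are group means with SD. The moribund arrays lay at -4.45 ± 0.12, and control 3, at -3.11, lay among the 24 h arrays.

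Values were scaled to each array's 75th percentile. With the median in place of it, the log2 fold changes of all probes moved by a median of -0.81 at 6 h, -0.64 at 24 h, -0.42 at 48 h and 0.63 at the moribund stage against control. The same choice moved them by 0.17 in 24 h vs 6 h, 0.21 in 48 h vs 24 h and 1.05 in moribund vs 48 h. Quantile normalization moved them by a median of -0.22, -0.21, -0.13 and 0.26 in the 4 comparisons with control and by 0.46 in moribund vs 48 h. A percentile over probes detected on all arrays moved them by 0.21 at 6 h, 0.11 at 24 h, 0.11 at the moribund stage, -0.13 in 48 h vs 24 h and 0.13 in moribund vs 48 h. Changes are given relative to these scalings.

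A single target, DV018450, was annotated to WSSV. On the log2 scale, it lay at -5.10 ± 0.47 (SD, n = 4) in control gills, where 0 of 4 arrays were well above background. At 6 h it lay at -3.98 ± 1.96 (n = 3), also with 0 arrays well above background. All 9 later infected arrays were well above background, at -0.11 ± 1.14 at 24 h, 1.22 ± 1.26 at 48 h and -1.49 ± 0.37 at the moribund stage. Where 0 arrays of a group were well above background, folds are given as bounds, against the higher of the probe's own signal and the lowest signal well above background on each array.

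**Figure D2:**
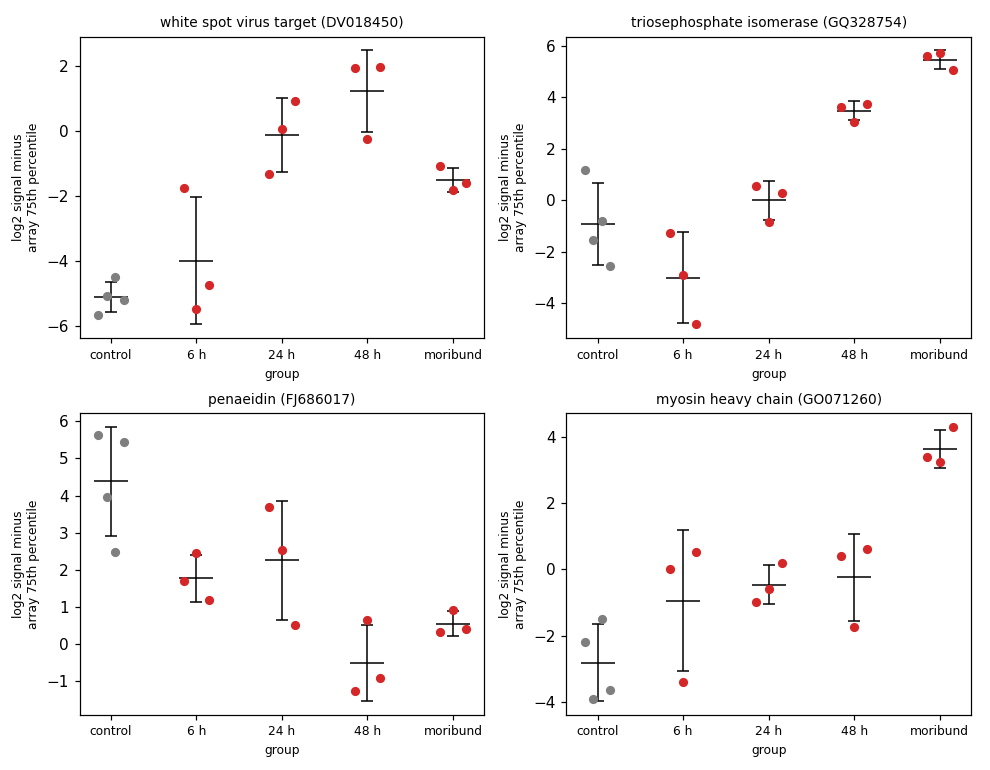
Log2 signal minus the array's 75th percentile (vertical axis) of 4 targets in the 5 groups (horizontal axis); points are arrays, and bars are group means with SD. The WSSV target stood at -5.10 in control gills and 1.22 at 48 h, and the triosephosphate isomerase target at -0.93 and 5.46 in control and moribund gills.

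Each infected group was compared with the same 4 controls, whose labels state no time or mock treatment. Time and handling are thus not separated from infection. At 6 h, no named target passed the threshold. The 3 with the smallest p were a BCS-1 homologue (GO067462), known from barnacle larvae, at a log2 fold change of 4.73 ± 0.84 (SE, n = 3 and 4; at least 8.09-fold), cytochrome c oxidase subunit II (GO076647), of the respiratory chain, at -4.49 ± 0.92, and a Kruppel-like factor (JF927714), a transcription factor, at -3.06 ± 0.72. All 3 had a limma adjusted p of 0.198. The WSSV target differed by 1.12 ± 0.84 (adjusted p = 0.314), with 0 arrays of either group well above background.

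Over all probes, limma called 0 at 6 h, with 3943 probes (25.1%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.160. Blocked by slide it called 0 (992 unadjusted), within the slide 0 (316), with scan session as a block 0 (706) and within session 1 0 (649). Without 6 h 2, 7842 probes were called. Targets of 3' reads had a median log2 fold change of 1.07 and those of 5' reads -0.75, and opposite-strand probes of 3' reads 1.26 against 0.12 for same-strand ones.

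At 6 h, limma's camera, with a preset correlation, called 7 of the 29 gene lists. Antimicrobial peptides and lysozymes (42 targets, median log2 fold change -1.27, adjusted p = 0.023), haemocyte markers (40, -1.40, adjusted p = 0.0159) and cytosolic ribosomal proteins (181, of which 150 from 3' reads, -0.86, adjusted p = 0.000146) fell. For these 3 lists adjusted p = 0.697 with an estimated correlation. Mitochondrial transcripts (262, of which 237 from 3' reads, 0.99, adjusted p = 0.00342), haemocyanin and clotting (8, 7 from 3' reads, 2.06, adjusted p = 0.0289), hepatopancreas markers (22, 14 from 3' reads, 1.20, adjusted p = 0.0289) and cuticle (54, 31 from 3' reads, 1.10, adjusted p = 0.00316) rose. Of these 4, the mitochondrial list had adjusted p = 0.739 and the others 0.697 with an estimated correlation. Hepatopancreas and muscle markers stand for tissues other than gill. None of the 7 lists had a member past the threshold over all probes (0 up, 0 down, all members not passing), and adjusted over the list alone 1 mitochondrial transcript passed, downward, and 0 members of the other 6.

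Among members with the smallest p at 6 h, all at an adjusted p of 0.198, were lysozyme (AF539466, an enzyme that cleaves bacterial cell walls) at -2.85 ± 0.92, prophenoloxidase 2 (EU853256, an enzyme of melanisation) at -2.82 and a haemocyanin (GO074810, the oxygen carrier of crustacean blood) at 3.44, at least 4.19-fold. Slide as a block called 5 lists and the slide alone 6. With scan session as a block 2 were called and within session 1 2: ribosomal proteins fell (adjusted p = 3.91e-09 with the block), and the mitochondrial list moved the other way, fell, at adjusted p = 1.24e-07 with the block and 3.11e-07 within session 1. Both values rest on control 3, where the mean level of that list was above those on control 1, 2 and 4 (-0.95, -0.15 and -0.40). That list also moved downward, without passing, with scaling within each read end (adjusted p = 0.405), with the strand index as a covariate (adjusted p = 0.914) and without targets of 3' reads (adjusted p = 0.617), and cuticle moved downward within session 1 (adjusted p = 0.759). Without 6 h 2, 11 lists were called, and 4 without control 4 or 6 h 3. The calls lost were antimicrobial peptides and haemocyte markers without 6 h 3 (adjusted p = 0.0934 for both), mitochondrial transcripts without control 1 (0.147), cuticle without control 4 (0.0503), hepatopancreas markers without control 4 or 6 h 1 (0.0567 to 0.117), and haemocyanin without control 3, control 4, 6 h 1 or 6 h 3 (0.0567 to 0.194). A further list, of 4 apoptosis targets (adjusted p = 0.186), had 1 member up and 3 down when adjusted over the list alone.

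The next comparison was 24 h with control. The WSSV target rose by 4.99 ± 0.84 on the log2 scale (limma adjusted p = 0.0362, higher in 3 of 3 arrays than in all 4 controls), at least 10.8-fold with each array's own floor. It was the only named target past the threshold. The next by p were 2 targets of cytochrome c oxidase subunit III, of the respiratory chain, that did not pass: GO079176 at 3.35 ± 0.62 (adjusted p = 0.0927) and GO067276 at 3.01 ± 0.68 (adjusted p = 0.262). The call of the WSSV target kept its direction in all 19 other settings and passed in 9 of them, with adjusted p from 0.00795 to 1.00. It did not pass with slide as a block (4.73, adjusted p = 0.56), within the slide (4.73), with scan session as a block or within session 1 (4.39), with the strand index as a covariate (3.74), with median or quantile scaling (4.35 and 4.92), with normexp (0.92), with the common floor (1.87) or with a replicate block (4.96). Without any 1 of moribund 1, 2 or 3, 48 h 1 or 3, control 1, 2 or 4, 6 h 3, or 24 h 2 or 3 its adjusted p rose to between 0.0585 and 0.541.

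At 24 h, 7 probes rose and 0 fell, for 7 targets, and 2824 probes had an unadjusted p under 0.05. There were 3 called with slide as a block, and 0 within the slide, with scan session as a block and within session 1. Without control 3, 1172 probes were called. The count was 3 without control 1, 2 or 4 or 24 h 2 or 3, and 4 without 48 h 3 or moribund 1, 2 or 3. Chosen after values were seen, the unnamed target DW404776 rose by 11.17 ± 1.28 (adjusted p = 0.00167, at least 956-fold) and EE661649 by 9.03 ± 1.09 (adjusted p = 0.00179). Both passed without each array in turn and with slide as a block (adjusted p = 0.0197), but not within the slide (0.32) or with scan session as a block (0.603), over a range of 4.43e-05 to 1.00 for the former. Targets of 3' reads had a median of 0.90 and those of 5' reads -0.38.

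Camera called 6 lists at 24 h, in which 0 members passed over all probes. Mitochondrial transcripts rose, with a median of 2.11 (adjusted p = 5.02e-26), and adjusted over the list alone 131 members were up and 0 down (adjusted p = 0.844 with an estimated correlation). Cuticle (1.35, adjusted p = 0.00192) and hepatopancreas markers (1.16, adjusted p = 0.0417) rose, both at adjusted p = 0.844 with an estimated correlation. Antimicrobial peptides (-0.76, adjusted p = 0.00441), haemocyte markers (-0.95, adjusted p = 0.00334) and translation factors (47 targets, 29 from 3' reads, -0.55, adjusted p = 0.0193) fell, and adjusted over the list alone 0 members of these 5 lists passed. For the last 3 lists, too, adjusted p = 0.844 with an estimated correlation. Examples that did not pass (adjusted p = 0.262) were cytochrome b (GO080856, of the respiratory chain) at 3.18, penaeidin 3b (FJ686017, an antimicrobial peptide) at -2.13 and peroxinectin (AF188840, a cell adhesion protein of haemocytes) at -2.06.

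At 24 h 7 lists were called with slide as a block, within the slide 8, and with scan session as a block and within session 1 0, where the mitochondrial list had adjusted p = 0.162 and 0.0856. Cuticle moved downward, without passing, with the scan block (adjusted p = 0.672) and within session 1 (adjusted p = 0.613), and hepatopancreas markers with the strand index as a covariate (adjusted p = 0.931). Without 24 h 2, 3 lists were called. Calls were lost for antimicrobial peptides and haemocyte markers without 24 h 3 (adjusted p = 0.333 and 0.141), translation factors without control 4 or 24 h 2 (0.0913 to 0.125), hepatopancreas markers without 48 h 3, control 2, 3 or 4 or 24 h 2 (0.0514 to 0.134), and cuticle without 24 h 2 (0.146).

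At 48 h, the comparison with control gave named targets in both directions. The WSSV target rose by 6.32 ± 0.84 (limma adjusted p = 0.00117, n = 3 and 4), at least 27.2-fold, and passed without each array in turn. Triosephosphate isomerase, a glycolytic enzyme, rose in 3 targets: CO777374 by 4.69 ± 0.84 (adjusted p = 0.0145), GQ328754 by 4.40 ± 0.86 (adjusted p = 0.028) and GO073593 by 4.37 ± 0.94 (adjusted p = 0.0434). Penaeidins, the antimicrobial peptides of penaeid haemocytes, fell: penaeidin 3b (FJ686017) at -4.89 ± 0.85 (adjusted p = 0.0129), from 4.38 ± 1.46 to -0.51 ± 1.02 (SD), and CN654917 at -4.69 ± 0.79 (adjusted p = 0.00988). The penaeidin targets CN654890 (-5.34 ± 1.16, adjusted p = 0.0458), BI018079 (-5.24 ± 1.13, adjusted p = 0.0447) and CN654897 (-4.21 ± 0.86, adjusted p = 0.0328) fell too.

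A target named after chromosome 10 open reading frame 56 (GO070610), whose probe matched the opposite strand, rose at 48 h by 5.17 ± 0.72 (adjusted p = 0.00157, at least 15.7-fold) and passed without each array in turn. A GTP binding protein (AI253800, of signalling) rose by 4.17 ± 0.89 (adjusted p = 0.0426) and thioredoxin-1 (GO071398, an antioxidant protein) by 3.06 ± 0.61 (adjusted p = 0.0319). A target whose description breaks off after "mitochond" (CK901445) fell, at -7.54 ± 1.47 (adjusted p = 0.0272). Chosen after values were seen, the unnamed targets EE661649 (10.88 ± 1.09) and GR976288 (10.03 ± 1.06, at least 506-fold) rose, both at adjusted p = 0.000199 and without each array in turn, and DW677996 (-4.95, adjusted p = 0.0138) and GO080448 (-2.93, adjusted p = 0.0221) fell.

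Leaving out 1 array ended calls of named targets at 48 h. CO777374 and GQ328754 did not pass without 48 h 1, 48 h 3, control 2 or control 4 (adjusted p 0.0597 to 0.131 and 0.0866 to 0.189), FJ686017 and DW677996 without 48 h 1, 48 h 3, control 1 or control 4 (0.0519 to 0.117 and 0.0519 to 0.131), and CN654917 without 48 h 1 or 48 h 3 (0.0845 to 0.0984). CK901445 and GO080448 did not pass without 48 h 1, 48 h 3 or control 1, 2 or 4 (0.0738 to 0.236 and 0.0559 to 0.198). CN654897 and GO071398 did not pass without moribund 1, 2 or 3, 48 h 1 or 3, control 1, 2 or 4 or 24 h 2 (0.0521 to 0.235 and 0.0513 to 0.209), and CN654890 and BI018079 without those or 6 h 1 (0.0586 to 0.398 and 0.0581 to 0.394). GO073593 did not pass without moribund 1, 2 or 3, 48 h 1, 2 or 3, control 2 or 4, 6 h 1 or 24 h 1, 2 or 3 (0.0523 to 0.319), and AI253800 without moribund 2 or 3, 48 h 1, 2 or 3, control 1, 2 or 4, 6 h 3 or 24 h 1, 2 or 3 (0.0515 to 0.375).

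With scan session as a block, which compares the 48 h arrays with control 3 alone, 0 probes were called and no named target passed. The WSSV target was then at 5.72 (adjusted p = 0.391), triosephosphate isomerase at 4.20 to 4.31 and penaeidin 3b at -3.00. The slide block left the WSSV target (6.58, adjusted p = 0.00578), GO070610, AI253800, CN654917 and penaeidin 3b (-5.31, adjusted p = 0.0272) past the threshold. The 3 triosephosphate isomerase targets (3.64 to 4.02), CK901445 (-7.62), CN654890 (-5.93) and BI018079 (-5.74) did not. With the strand index as a covariate the WSSV target (4.99, adjusted p = 0.00955) and GO070610 (4.00) passed, penaeidin 3b (-3.77) and the 3 triosephosphate isomerase targets (3.15 to 4.16) did not. Normexp ended the calls of the WSSV target (1.69) and GO070610 (1.06). Over all other settings the adjusted p of the WSSV target ranged from 0.000434 to 0.680. Calls were kept in 13 of 19 other settings for CO777374, 12 for GQ328754, 9 for GO073593, 10 for AI253800, 15 for FJ686017 and 14 for CN654917 and DW677996. They were kept in 11 of 19 for CK901445, CN654890, BI018079 and CN654897, in 17 for EE661649 and GR976288, and, of 18, in 12 for GO080448 and 8 for GO071398.

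At 48 h, limma called 89 probes, 49 higher and 40 lower (55.1% higher), with 2202 at an unadjusted p under 0.05. Median scaling gave 32 higher and 7 lower. Slide as a block gave 87 probes, of which 41 were among the 89, and the comparison within the slide 394. Scan session as a block gave 0, and session 1 alone 0. Leaving out 1 array gave 893 without control 3, 153 without 6 h 2, 58 without moribund 1, 58 without moribund 3, 57 without 24 h 2, 43 without control 2, 33 without control 1, 29 without control 4, 27 without 48 h 1 and 19 without 48 h 3. Targets of 3' reads had a median of 0.70 and those of 5' reads -0.32.

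Among gene lists at 48 h, antimicrobial peptides fell (median -1.16, 0 up, 6 down, 36 not passing, adjusted over the list alone 0 up and 9 down, camera adjusted p = 2.98e-06), as did haemocyte markers (-0.58, 0 up, 6 down, 34 not passing, adjusted over the list alone 1 up and 8 down, adjusted p = 3.31e-06). These lists share 15 targets. For both, adjusted p = 0.604 with an estimated correlation. Mitochondrial transcripts (1.06, adjusted p = 1.59e-08; adjusted p = 0.905 with an estimated correlation) and hepatopancreas markers (1.34, adjusted p = 7.15e-05; adjusted p = 0.672 with an estimated correlation) rose. Translation factors fell (-0.43, adjusted p = 0.0336; adjusted p = 0.905 with an estimated correlation). In these 3 lists 0 members passed, over all probes or adjusted over the list alone.

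Antimicrobial peptides and haemocyte markers also fell at 48 h against the 2 controls of the same slide (adjusted p = 1.29e-05 for both with slide as a block), against control 3 alone (0.0147 and 0.0151 with the scan block, 0.0218 for both within session 1) and with the strand index as a covariate (0.0029 and 0.00704). Over the 20 other settings their adjusted p ranged from 5.58e-09 to 0.604 and from 1.42e-08 to 0.604. The mitochondrial list moved the other way, fell, with the scan block (adjusted p = 0.000931) and within session 1 (adjusted p = 0.00130), and did not pass with the strand index (0.455). Hepatopancreas markers did not pass with the scan block (0.0741), within session 1 (0.0753) or with the strand index (0.444), nor did translation factors with slide as a block (0.333), within the slide (0.373), with the scan block (0.731) or within session 1 (0.786). In all, 5 lists were called with slide as a block, 4 within the slide, and 6 with the scan block and within session 1. The call of translation factors was lost without 48 h 1, 48 h 3, control 3 or control 4 (adjusted p 0.0511 to 0.220).

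**Figure D3:**
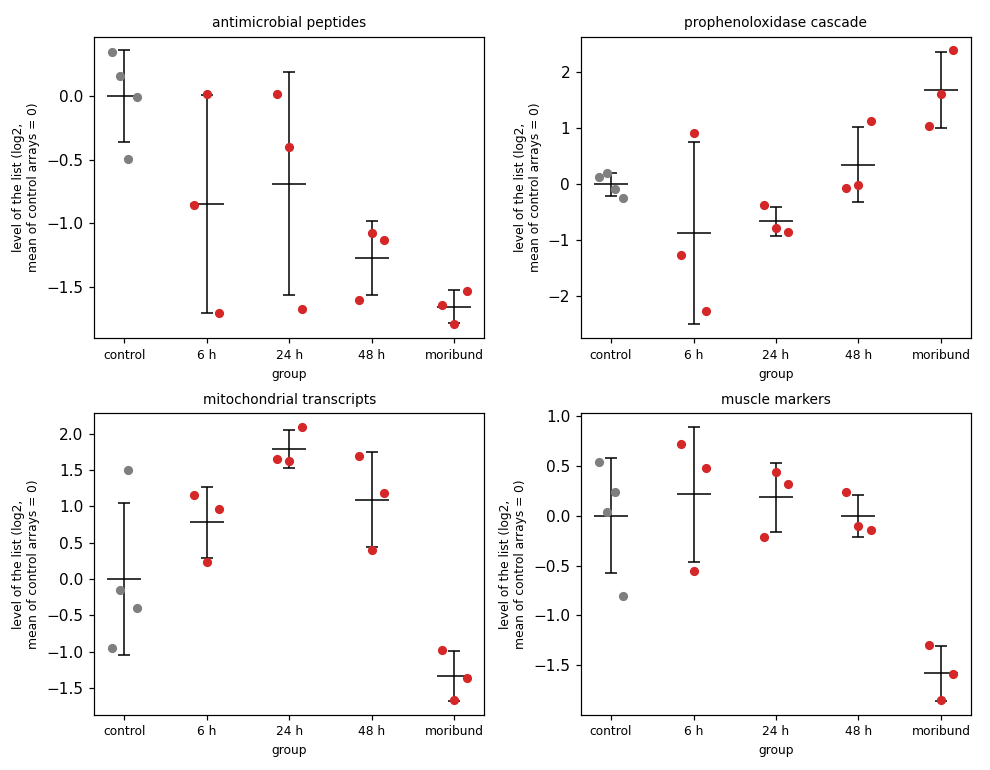
Mean log2 value of 4 gene lists per array, relative to the mean of the control arrays (vertical axis), in the 5 groups (horizontal axis); points are arrays, and bars are group means with SD. The lower antimicrobial peptides at 48 h and in moribund gills and the lower muscle markers in moribund gills were camera calls that ended with an estimated correlation (adjusted p = 0.604, 0.402 and 0.353).

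The comparison of the moribund stage with control covers the end of the infection. Triosephosphate isomerase rose in 3 targets: CO777374 by 6.95 ± 0.84 (limma adjusted p = 0.000143), GO073593 by 6.60 ± 0.94 (adjusted p = 0.00058) and GQ328754 by 6.38 ± 0.86 (adjusted p = 0.00035), the last from -0.93 ± 1.58 (SD, n = 4) to 5.46 ± 0.36 (n = 3). A muscle myosin heavy chain (GO071260, a motor protein of muscle) rose by 6.45 ± 0.91 (adjusted p = 0.000546), a target with a description that breaks off after "Low-density" (GW775493) by 5.90 ± 0.85 (adjusted p = 0.00059, at least 32.8-fold) and a prophenoloxidase activating enzyme (GO082076, which starts melanisation) by 5.86 ± 1.00 (adjusted p = 0.00272). These 6 passed without each array in turn and with slide, scan session or the strand index in the fit. The exceptions were within session 1, with adjusted p = 0.0502 for GO071260 (5.15) and 0.0513 for GO082076 (6.05).

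Penaeidins fell in moribund gills: a penaeidin 3b target (GW996646) at -4.08 ± 0.65 (adjusted p = 0.00142, lower in 3 of 3 arrays), CN654894 at -4.45 ± 1.05 (adjusted p = 0.0286), penaeidin 5 (FJ686018) at -4.45 ± 0.96 (adjusted p = 0.017), CN654897 at -4.32 ± 0.86 (adjusted p = 0.00948) and CN654917 at -3.88 ± 0.79 (adjusted p = 0.0111). GW996646 passed without each array in turn, but not with scan session as a block (-2.77, adjusted p = 0.0503) or within session 1 (adjusted p = 0.0758). CN654894 did not pass without moribund 1, 2 or 3 or control 1, 2 or 4 (0.0552 to 0.142), FJ686018 without moribund 1, moribund 3 or control 2 (0.0556 to 0.103), CN654897 without moribund 2 or 3 (0.0509 to 0.0534) and CN654917 without moribund 1 or 3 (0.0635 to 0.066). With scan session as a block CN654894 (-3.00, adjusted p = 0.152) and FJ686018 (-2.33, adjusted p = 0.184) did not pass, and with slide as a block CN654894 did not (-4.92, adjusted p = 0.064). Their adjusted p over all other settings ranged from 0.000516 to 0.185 and from 0.00127 to 0.219. CN654897 and CN654917 each kept the call in 16 of 19 other settings and lost it with median scaling, with the scan block and in session 1 alone (adjusted p up to 0.15 and 0.151).

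CK901445, described as "mitochond", fell in moribund gills, at -8.65 ± 1.47 (adjusted p = 0.00265), and passed without each array in turn, but not within session 1 (-7.69, adjusted p = 0.0668). A LIM protein (GO073989, a muscle protein) fell at -6.82 ± 1.44 (adjusted p = 0.0141, at least 39.4-fold), a sarcoplasmic calcium-binding protein (GO082364, of muscle) at -6.76 ± 1.73 (adjusted p = 0.0477, at least 43.1-fold) and NADH dehydrogenase subunit 1 (GO074083, of the respiratory chain) at -4.54 ± 1.14 (adjusted p = 0.0439). The LIM protein did not pass without moribund 1, 2 or 3 (0.052 to 0.0834). GO082364 did not pass without moribund 1, 2 or 3, 48 h 1, 2 or 3, control 2, 6 h 1 or 3 or 24 h 1, 2 or 3 (0.0537 to 0.193), and GO074083 without moribund 1, 48 h 1, 2 or 3, control 1, 2, 3 or 4, 6 h 1 or 24 h 1, 2 or 3 (0.0512 to 0.16). With scan session as a block the LIM protein (-2.68), GO082364 (-2.49) and GO074083 (-3.87) did not pass, and with slide as a block GO074083 (-4.85) did not. The LIM protein kept its call in 13 of 18 other settings, GO082364 in 10 of 18 and GO074083 in 10 of 19, with adjusted p up to 0.424, 0.470 and 0.141.

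The WSSV target rose in moribund gills by 3.61 ± 0.84 (adjusted p = 0.0269, higher in 3 of 3 arrays), at least 4.13-fold with each array's own floor. It did not pass with slide as a block (3.86, adjusted p = 0.0754) or scan session as a block (3.00, adjusted p = 0.0955), within session 1 (3.00), with the common floor (0.49) or with normexp, which gave -0.20, and its adjusted p over all other settings ranged from 0.00107 to 0.828. Without moribund 1, 2 or 3 or control 1, 2 or 4 it did not pass (0.0572 to 0.123). Chosen after values were seen, the unnamed targets GW994343 (11.66 ± 0.70, adjusted p = 8.42e-08, at least 1286-fold) and DW042882 (9.05 ± 0.72, adjusted p = 3.01e-06, at least 294-fold) rose and passed in all 19 other settings and without each array in turn. The unnamed targets DT366712 (-8.79, adjusted p = 0.000273) and GO073977 (-4.20, adjusted p = 0.000243) fell and passed without each array in turn. GO073977 did not pass with the common floor (-0.02).

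Among further targets in moribund gills, a clip domain serine proteinase (FJ620688, of the melanisation cascade) rose by 3.45 ± 0.69 (adjusted p = 0.00948; without moribund 1 or 3 0.0539 to 0.0626). A serine proteinase inhibitor (GU358488) rose by 4.17 ± 0.97 (adjusted p = 0.0264; without moribund 1, 2 or 3 or control 2 or 3 0.0548 to 0.199), and cathepsin L (EF213115, a lysosomal protease) by 3.08 ± 0.71 (adjusted p = 0.0254; without moribund 1, 2 or 3 or control 2 or 4 0.0553 to 0.138). Thioredoxin rose in 3 targets, by 3.24 (GO071398, adjusted p = 0.00669; without moribund 1 0.0509), 3.75 (JF828310, adjusted p = 0.0135; without moribund 1, 2 or 3 0.0521 to 0.0764) and 3.43 (GO066363, adjusted p = 0.0141; without moribund 1, 2 or 3 0.0598 to 0.0806). Ribosomal protein L24 (GO080172) rose by 5.18 ± 1.15 (adjusted p = 0.0205; without moribund 1, 2 or 3 or control 4 0.0506 to 0.128). Cytochrome b fell in 2 targets, GO077521 (-3.56 ± 0.62, adjusted p = 0.0033, without each array in turn too) and GO069534 (-4.10, adjusted p = 0.00649; without moribund 2 0.0581), while NADH dehydrogenase subunit 6 (GO068978), of the same organelle, rose by 4.71 ± 0.93 (adjusted p = 0.00888; without moribund 1 0.0586). Of 19 other settings the call was kept in 17 for FJ620688, 14 for GU358488, 16 for EF213115 and 18 for JF828310. Of 18, it was kept in 16 for GO071398 and GO066363, in 15 for GO080172, GO069534 and GO068978, and in 18 for GO077521.

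At the moribund stage, limma called 380 probes, 241 higher and 139 lower (63.4% higher), with 3141 at an unadjusted p under 0.05. Median scaling gave 323 higher and 62 lower, and quantile normalization 330 and 94. Slide as a block gave 270 probes, 126 higher and 144 lower, of which 188 were among the 380, and the comparison within the slide 455. Scan session as a block gave 1746, and session 1 alone 629. Leaving out 1 array gave 199 without moribund 1, 165 without moribund 2, 187 without moribund 3 and 772 without 6 h 2. Targets of 3' reads had a median of -1.03 and those of 5' reads 0.24.

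Camera called 8 lists in moribund gills. Antimicrobial peptides fell (median -1.57, 0 up, 9 down, 33 not passing, adjusted over the list alone 0 up and 14 down, adjusted p = 0.000115; adjusted p = 0.402 with an estimated correlation). Mitochondrial transcripts fell (-1.24, 1 up, 3 down, 258 not passing, adjusted over the list alone 1 up and 2 down, adjusted p = 7.12e-12; adjusted p = 0.451 with an estimated correlation). Muscle markers fell too (95 targets, 70 from 3' reads, -1.23, 1 up, 2 down, 92 not passing, adjusted over the list alone 1 up and 11 down, adjusted p = 3.08e-06; adjusted p = 0.353 with an estimated correlation). Cuticle (-1.16, 0 up, 1 down, 53 not passing, adjusted over the list alone 0 up and 2 down, adjusted p = 0.00397; adjusted p = 0.634 with an estimated correlation) and haemocyanin and clotting (-1.95, 0 up, 0 down, 8 not passing, adjusted over the list alone 0 up and 1 down, adjusted p = 0.0333; adjusted p = 0.599 with an estimated correlation) fell as well. The prophenoloxidase cascade rose (15 targets, 1.19, 2 up, 0 down, 13 not passing, adjusted over the list alone 4 up and 0 down, adjusted p = 0.00171; adjusted p = 0.402 with an estimated correlation). The ubiquitin and proteasome list rose (41 targets, 0.47, 1 up, 0 down, 40 not passing, adjusted over the list alone 9 up and 0 down, adjusted p = 0.00171; adjusted p = 0.353 with an estimated correlation). Endocytosis and virus entry rose (25 targets, 0.85, 0 up, 0 down, 25 not passing, adjusted over the list alone 0 up and 0 down, adjusted p = 0.00913; adjusted p = 0.402 with an estimated correlation). Fry, which asks whether a list's members move 1 way on balance, called antimicrobial peptides (adjusted p = 0.0384) and muscle markers (adjusted p = 0.0145).

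Members named in these lists include troponin I (GO069900, a muscle protein), which fell at -3.40 ± 0.86 (adjusted p = 0.0444, at least 5.29-fold), cuticle protein AMP4 (GO075463), which fell at -4.20 ± 1.02 (adjusted p = 0.0363), and a ubiquitin hydrolase (FE043463), which rose by 2.51 ± 0.65 (adjusted p = 0.0498). Troponin I did not pass without moribund 1, 2 or 3, 48 h 1 or 3, control 2, 3 or 4, 6 h 3 or 24 h 1, 2 or 3 (0.0504 to 0.269). The cuticle protein did not pass without moribund 1 or 2, control 1, 2 or 4 or 24 h 3 (0.0509 to 0.185), nor the hydrolase without moribund 1, 2 or 3, 48 h 1, 2 or 3, control 2 or 3 or 24 h 1, 2 or 3 (0.0626 to 0.285). Over other settings troponin I (GO069900) kept its call in 10 of 17 (log2 fold change up to -0.15, adjusted p up to 0.86), the cuticle protein (GO075463) in 8 of 18 (up to 0.195) and the hydrolase (FE043463) in 8 of 19 (up to 0.169). Slide as a block called 9 lists and the slide alone 11. With scan session as a block and within session 1, both with control 3 as the only control, 3 were called: muscle markers (adjusted p = 0.0019 and 0.000637), mitochondrial transcripts (1.58e-18 and 3.73e-18) and cuticle (0.000524 and 2.26e-05). The scan block ended the calls of antimicrobial peptides (0.263), the prophenoloxidase cascade (0.059), ubiquitin and proteasome (0.184), haemocyanin (0.138) and endocytosis (0.167). The strand index as a covariate ended those of cuticle (0.0518) and haemocyanin (0.14). Haemocyanin did not pass without moribund 2, control 1 or control 3 (0.0528 to 0.0878), nor cuticle without control 2 or 3 (0.0641 to 0.0662).

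The comparison of 24 h with 6 h asks what differs between the first sampling points. None of the named targets passed. The 3 with the smallest p, all at a limma adjusted p of 0.426, were cytochrome c oxidase subunit III (GO066502) at -3.37 ± 0.77 (SE, n = 3 and 3; at least 3.48-fold lower), the WSSV target at 3.87 ± 0.90 (at least 7.19-fold higher) and a ribonuclease (GW775437, an RNA-cleaving enzyme) at -3.79 ± 0.91. Limma called 0 probes, with 1076 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0931. Slide as a block, the slide alone, scan session as a block and session 1 alone gave 0 each, with the same fold changes, since both groups shared the slide and the session. Leaving out 1 array gave 6 without 6 h 1, 3 without 6 h 2 and 1 without 24 h 1.

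Camera called 2 lists in 24 h vs 6 h, both upward and with 0 members past the threshold, over all probes or adjusted over the list alone: mitochondrial transcripts (median 1.06, adjusted p = 2.82e-16) and cytosolic ribosomal proteins (0.67, adjusted p = 9.25e-07). For both, adjusted p = 0.978 with an estimated correlation. Slide as a block (adjusted p = 1.03e-16 and 1.06e-06), the slide alone (2.21e-16 and 4.19e-06), scan session as a block (2.14e-17 and 6.98e-07) and session 1 alone (2.84e-17 and 5.26e-07) called both. Without targets of 3' reads the ribosomal list did not pass (0.0686), nor with normexp (0.204). It did not pass without 6 h 1 or 6 h 3 (0.0601 to 0.121), when 1 list was called, and 4 lists were called without 6 h 2.

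The comparison of 48 h with 24 h had 1 named target past the threshold. GO070610, with its opposite-strand probe, rose by 4.49 ± 0.77 (limma adjusted p = 0.0282, n = 3 and 3), at least 7.76-fold. Thioredoxin-1 (GO071398) at 3.08 ± 0.66 (adjusted p = 0.195), a granulin (GO081925, a secreted growth factor) at 3.07 ± 0.68 (adjusted p = 0.235) and the WSSV target at 1.34 ± 0.90 (adjusted p = 0.999) did not pass. The call of GO070610 was lost with slide as a block (4.30, adjusted p = 0.706), within session 1 (4.49, adjusted p = 0.094), with normexp (0.86) and with a percentile over detected probes (4.36), over a range of 0.00156 to 0.820 in the other settings. It was lost without moribund 1 or 3, 48 h 1 or 3 or 24 h 1, 2 or 3 (0.0502 to 0.29).

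In 48 h vs 24 h, 13 probes rose and 0 fell, with 559 at an unadjusted p under 0.05. Slide as a block gave 9, scan session as a block 13 and session 1 alone 7. Each group lay on its own slide, so no comparison within a slide was possible. Leaving out 1 array gave 0 without 48 h 3 or 24 h 2, 1 without 48 h 1, 2 without 24 h 1 and 3 without 24 h 3. Chosen after values were seen, the unnamed target EL595648 rose by 7.59 ± 0.98 (adjusted p = 0.00894; without 48 h 3 or 24 h 2 0.0921 to 0.135) and GW994343 by 5.21 ± 0.75 (adjusted p = 0.0169, at least 16.4-fold; without 48 h 1 or 3 or 24 h 1 or 2 0.0697 to 0.136). In the slide block EL595648 was at 10.78 (adjusted p = 0.00236) and GW994343 did not pass (5.21, adjusted p = 0.252).

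Camera called 8 lists in 48 h vs 24 h, in which 0 members passed over all probes. Mitochondrial transcripts fell (median -0.81, adjusted p = 8.08e-14), as did cuticle (-0.80, adjusted p = 0.00916), antimicrobial peptides (-0.48, adjusted p = 0.0161) and haemocyte markers (-0.40, adjusted p = 0.0377), and the prophenoloxidase cascade rose (0.79, adjusted p = 0.00916). For these 5, adjusted p = 0.806 with an estimated correlation. The cytoskeleton list (51 targets, -0.64, adjusted p = 0.00916) and histones (14 targets, -0.53, adjusted p = 0.0314) fell and antioxidant enzymes (32 targets, 0.39, adjusted p = 0.0244) rose. For these 3, adjusted p = 0.401 with an estimated correlation. Adjusted over the list alone, 2 antioxidant targets were up, and 0 members of the others passed. With slide as a block 5 lists were called, and with scan session as a block and within session 1 8. The slide block ended the calls of the prophenoloxidase cascade (adjusted p = 0.57), antioxidant enzymes (0.371), cuticle (0.167) and histones (0.302) and turned the mitochondrial list upward (adjusted p = 0.398).

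In the same comparison 3 lists were called without 24 h 1. Antimicrobial peptides did not pass without 48 h 1, 24 h 1 or 24 h 2 (0.154 to 0.533), the prophenoloxidase cascade without 48 h 3 (0.102), antioxidant enzymes without 48 h 1 or 24 h 1 (0.0964 to 0.157), and haemocyte markers without 48 h 1, 6 h 2, 24 h 1 or 24 h 2 (0.0572 to 0.465). Cuticle did not pass without 24 h 2 (0.82), histones without 48 h 2 or 24 h 1 (0.212 to 0.274) and the cytoskeleton list without 48 h 1 or 24 h 1 (0.0595 to 0.0919).

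The comparison of moribund with 48 h gills had the highest count of calls. Among the named targets, an envelope glycoprotein (LSGUSF39, a name given to retroelement and virus proteins) rose by 4.78 ± 0.78 (limma adjusted p = 0.0127, at least 14.9-fold), muscle myosin heavy chain (GO071260) by 3.87 ± 0.97 (adjusted p = 0.0178) and a thrombospondin (GW775338, an extracellular matrix protein) by 3.81 ± 0.66 (adjusted p = 0.0127). The calcified cuticle protein CP8.5 (GO073306) fell, at -6.67 ± 1.59 (adjusted p = 0.015), as did translation initiation factor 4A (GO079588) at -6.41 ± 1.49 (adjusted p = 0.0141) and a BCS-1 homologue (GO066817) at -6.34 ± 1.28 (adjusted p = 0.0127, at least 39.3-fold with each array's own floor). The WSSV target fell, at -2.72 ± 0.90 (adjusted p = 0.0396). The 75th percentile subtracted from each array was on average 2.40 higher on the moribund than on the 48 h arrays, close to that difference. The fall is therefore relative to the scaling and does not show a lower unscaled signal.

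With the strand index as a covariate LSGUSF39 (6.11, adjusted p = 0.00361), GO071260 (6.27) and GW775338 (4.27) passed in moribund vs 48 h. The covariate ended the calls of GO073306 (-1.76, adjusted p = 0.318), GO079588 (adjusted p = 0.3), GO066817 (-2.42, adjusted p = 0.121) and the WSSV target (-0.87, adjusted p = 0.616). The call of the WSSV target was also lost with median (-1.67) and quantile scaling (-2.50), with a percentile over detected probes (-2.59) and without targets of 3' reads (-2.72), over a range of 0.00228 to 0.616 in the other settings, and that of GO066817 with the common floor (-1.62). Slide and scan session as blocks left all 7 values as they were and past the threshold, since both groups shared the slide and the session. LSGUSF39 did not pass without moribund 2 or 3 (adjusted p 0.0612 to 0.084), nor did GO071260, GW775338, GO073306, GO079588 and GO066817 without moribund 2, moribund 3 or 48 h 1 (0.0612 to 0.0889), nor the WSSV target without moribund 1, 2 or 3 or 48 h 1 or 3 (0.065 to 0.148).

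In moribund vs 48 h, limma called 3598 probes, 798 higher and 2800 lower (22.2% higher), with 6498 at an unadjusted p under 0.05. Median scaling gave 2107 higher and 1219 lower, quantile normalization 626 and 885, and a percentile over detected probes 1119 and 2274. The strand index as a covariate left 65 probes, 49 higher and 16 lower. Slide as a block gave 3670, the slide alone 7229, scan session as a block 4997 and session 1 alone 4391. Leaving out 1 array gave 0 without moribund 2 or 3, 9 without 48 h 1, 837 without 48 h 3, 2047 without moribund 1 and 5553 without 6 h 2. Targets of 3' reads had a median of -1.76 (43 higher, 1581 lower) and those of 5' reads 0.77 (553 higher, 714 lower).

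Chosen after values were seen, the unnamed targets GE615809 (5.44 ± 0.70) and GE615570 (5.67 ± 0.74) rose in moribund vs 48 h, both at adjusted p = 0.00468 and in all 19 other settings, and GO081321 (-6.11, adjusted p = 0.0109) and GW995512 (-4.02, adjusted p = 0.0109, at least 6.09-fold with each array's own floor) fell. GE615809, GE615570 and GW995512 did not pass without moribund 2 or 3 (0.0612 to 0.084), nor GO081321 without moribund 2, moribund 3 or 48 h 1 (0.0606 to 0.084). The strand index as a covariate ended the call of GO081321 (-4.33), and quantile normalization (-1.78) and the common floor (0.00) that of GW995512.

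Camera called 8 lists in moribund vs 48 h, and for each adjusted p = 0.583 with an estimated correlation. Mitochondrial transcripts fell (median -2.40, 0 up, 143 down, 119 not passing, adjusted over the list alone 0 up and 182 down, adjusted p = 4.38e-17). Muscle markers fell (-1.79, 2 up, 22 down, 71 not passing, adjusted over the list alone 2 up and 25 down, adjusted p = 0.0065). Hepatopancreas markers fell (-2.33, 0 up, 8 down, 14 not passing, adjusted over the list alone 0 up and 9 down, adjusted p = 0.00818), as did cuticle (-1.37, 0 up, 14 down, 40 not passing, adjusted over the list alone 0 up and 16 down, adjusted p = 0.0065) and haemocyanin and clotting (-2.42, 0 up, 1 down, 7 not passing, adjusted over the list alone 0 up and 4 down, adjusted p = 0.0412). The prophenoloxidase cascade (2.01, 2 up, 1 down, 12 not passing, adjusted over the list alone 2 up and 1 down, adjusted p = 0.0308), heat shock proteins and chaperones (26 targets, 0.68, 6 up, 1 down, 19 not passing, adjusted over the list alone 6 up and 1 down, adjusted p = 0.0338) and translation factors (0.69, 3 up, 2 down, 42 not passing, adjusted over the list alone 2 up and 2 down, adjusted p = 0.0255) rose. Fry called the mitochondrial, muscle and hepatopancreas lists among these (adjusted p = 0.0136, 0.0136 and 0.034).

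With the strand index as a covariate the calls of cuticle (adjusted p = 0.442), hepatopancreas markers (0.527), translation factors (0.527) and the prophenoloxidase cascade (0.407) were lost in moribund vs 48 h and haemocyanin moved upward (adjusted p = 0.960), while mitochondrial transcripts (3.02e-10), muscle markers (0.0426) and heat shock proteins (0.0331) passed. With slide as a block 9 lists were called, within the slide 8, with scan session as a block 7 and within session 1 8, and haemocyanin did not pass with the scan block (0.0609). Calls were lost for the prophenoloxidase cascade without moribund 3 or 48 h 2 (0.0868 to 0.0905), heat shock proteins without moribund 1 or 48 h 3 (0.0597 to 0.103) and haemocyanin without moribund 1 or 2, 48 h 1 or control 3 (0.0567 to 0.0615).

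The other 13 lists tested were called in none of the 7 comparisons, and their camera adjusted p ranged from 0.0522 to 0.999. Over the comparisons it ranged from 0.0588 to 0.968 for protease inhibitors (13 targets), 0.479 to 0.968 for pattern recognition (8), 0.152 to 0.676 for immune signalling (5), 0.138 to 0.968 for RNA interference (4), 0.169 to 0.900 for glycolysis (46) and 0.626 to 0.978 for the tricarboxylic acid cycle (3). It ranged from 0.091 to 0.999 for the nuclear-encoded respiratory chain (28), 0.619 to 0.968 for lipid metabolism (12), 0.0878 to 0.914 for apoptosis (4), 0.0644 to 0.968 for gill ion transport (12), 0.289 to 0.930 for DNA replication and cell cycle (7), 0.0522 to 0.857 for transposable elements (9) and 0.186 to 0.999 for hormones and moulting (18). The WSSV list (1 target) and the endoplasmic reticulum stress list (2 targets) were too small to test. An exact two-sided permutation test of each list's level per array, infected against control, could give no p below 0.0286 and gave none under 0.05 after adjustment over the 29 lists of a comparison.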

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

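Chosen only after the result was seen were the tests of the scaling, of opposite-strand signal, of a label swap and of virus transcripts; the tests of array brightness, of the scan session, of signal in control gills and of other splits of the arrays were written before.

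The first pattern is the 3598 probes called in moribund vs 48 h, most of them lower. The spike-in could not decide on a brightness shared with the sample, as its values overlapped. They were 10.62 to 11.73 (log2) on moribund and 10.02 to 11.79 on 48 h arrays. The means differed by 0.272, and the 75th percentile by 2.40. Nor does the spike-in measure the sample's own signal, so it cannot decide whether brighter signal moved dim probes through the scaling. The direction of most calls depended on the scaling. With median scaling 36.7% of called probes were lower, against 885 of 1511 with quantile normalization, 2274 of 3393 with the detected-probe percentile and 2800 of the 3598 here. A constant per array shifts this share by choice, so the tests could not decide which direction is right. Signal from the opposite strand stays open: with the strand index in the fit 65 probes were called, of which 51 were among the 3598. The median absolute log2 fold change of the 3598 fell from 3.14 to 1.35 while their median standard error went from 0.897 to 0.782. The calls ended because the fold changes shrank, and a change of the moribund gill itself that moves with the index is not tested by this.

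The second pattern is the many small unadjusted p at 6 h and 24 h beside few calls. The tables argue against a label swap of control 3 and 6 h 2 after the spike-in was added: the spike-in of 6 h 2 exceeded that of the highest control by 1.95, and that of control 3 lay below every infected array. An effect of the scan session or of control 3 stays open, because across probes control 3 minus control 4 correlated at 0.682 with 6 h minus the mean of control 1 and 2, which share no array; probes are not independent replicates. Opposite-strand signal may account for part of it: with the strand index in the fit 689 probes at 6 h and 630 at 24 h had an unadjusted p under 0.05, where chance gives 784.6. An effect of early infection is confounded with these in the design and was not tested apart.

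The third pattern is unnamed targets far higher in infected gills. Transcripts of the virus cloned in infected libraries are a candidate explanation that the counts could not decide: 6 of 1532 unnamed targets from such libraries and 26 of 9691 others rose at 48 h, an odds ratio of 1.46 (95% exact interval 0.491 to 3.64; Fisher exact p = 0.434). A general induction of transcripts present in uninfected gills stays open: 59.4% of those targets (19 of 32) were well above background on at least 1 control array, but this held for 2 of the 6 from infected libraries. The share among all targets tested was not counted, so the 59.4% alone is no evidence for it. The 2 explanations can hold for different targets.

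Other splits of the same arrays into groups of these sizes were counted, the real split included. For moribund vs control, 1 of the 35 splits called as many as 380 probes, the real one, and the highest other called 55. This met the share of under 0.05 set beforehand, but it is the smallest share that 35 splits allow, uncorrected over the counts tested. The control arrays also differed from the infected ones in spike-in signal and, except control 3, in scan session, so the share does not point to infection alone. For the 8 lists called in moribund vs control 9 of 35 splits gave as many (highest other 12), so chance was not excluded. At 6 h the real count was 0, reached by 35 of 35 splits (highest other 9562), and the 7 lists by 14 (highest other 13). At 24 h the 7 probes were reached by 3 of 35 (highest other 3814) and the 6 lists by 12 (highest other 11). At 48 h the 89 probes were reached by 3 of 35 (highest other 3822) and the 5 lists by 20 (highest other 9). In none of these 6 cases was chance excluded.

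Splits that called several times the real count point to a structure of the samples. The split with control 3 beside the infected arrays follows scan session and, except at the moribund stage, the strand index too, so its counts cannot be assigned to 1 of these. It called 4444 probes at 6 h, 3814 at 24 h, 2896 at 48 h and 0 at the moribund stage. With scan session as a block the real comparisons called 0, 0, 0 and 1746, but that block compares the infected arrays with control 3 alone, so these counts do not tell the session from control 3. The splits with the highest counts at 6 h (9562), 48 h (3822) and 24 h vs 6 h (2547) follow the strand index, as does the real split of moribund vs 48 h. Other splits that follow it, 1 at 24 h, 2 at the moribund stage and 1 in 48 h vs 24 h, called 0 probes, so the index does not go with high counts throughout. A further 2 splits at 6 h called 2901 each and follow neither session nor index, nor do 1 split at 6 h and 1 at 24 h that called 133 each. The same holds for 1 split in 24 h vs 6 h that called 39, against a real count of 0. With the index in the fit the real comparisons at 6 h, at 48 h, in 24 h vs 6 h and in moribund vs 48 h called 0, 25, 0 and 65.

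Comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05. The real counts of probes were 0 in 24 h vs 6 h (10 splits as high, highest other 2547), 13 in 48 h vs 24 h (1 split, highest other 0) and 3598 in moribund vs 48 h (1 split, highest other 0). The real counts of lists were 2 (9 splits, highest other 12), 8 (2 splits, highest other 11) and 8 (4 splits, highest other 9).

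Single control arrays lay far from the other 3 in 6 of 50 values tested, measured as the gap to the nearest array over the range of the group for 4 arrays; chance gives about 1 in 20. Control 1 was lowest for cytosolic ribosomal proteins (0.975) and cytochrome c oxidase subunit II, GO076647 (0.88). Control 3 was lowest for the penaeidins CN654890 (0.933), BI018079 (0.865), CN654894 (0.851) and FJ686018 (0.869).

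Some targets differed between infected groups by a direct limma comparison. GO070610 differed by 4.49 between 48 h and 24 h. Between moribund and 48 h gills the WSSV target DV018450 differed by -2.72, the GTP binding protein AI253800 by -6.18, myosin heavy chain GO071260 by 3.87, GW775493 by 3.67, the prophenoloxidase activating enzyme GO082076 by 3.83 and NADH dehydrogenase subunit 1 GO074083 by -4.33. These differences are relative to the scaling: the subtracted 75th percentile was 2.40 higher on the moribund arrays, close to the fall of DV018450. Limma called 0 probes in 48 h vs 24 h without 48 h 3 or 24 h 2, and 0 in moribund vs 48 h without moribund 2 or 3. With each array left out in turn the differences stayed at 4.15 to 5.10 for GO070610, -3.45 to -2.35 for DV018450 and 3.12 to 4.30 for GO071260, so the lost calls do not show that these rest on single arrays.

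A signal outside the main measurement was the E1A spike-in, added to the RNA and printed on each array. Its median log2 signal was 10.02 on the lowest infected array and 11.79 on the highest. On the 4 control arrays, control 3 included, it was 9.43 to 9.65. Infection is therefore confounded with the spike-in signal in every comparison with control. Neither use of the scan session removes this, because control 3, scanned with the infected arrays, lay below all of them. The cause of the difference in spike-in signal was not tested.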

How the results depend on the processing

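Chosen only after seeing the data were the detected-probe percentile, the common floor, both uses of the scan session, scaling within each read end, the strand covariate, leaving out 3' reads, 1 value per description and leaving out control 3 and 6 h 2 together. For 135 named values, 2132 of 2480 other settings kept direction and side of the threshold, 252 lost the call, 89 gained it and 5 changed sign uncalled. For 44 called lists, 600 of 866 kept the call and 253 lost it. The settings eBayes with trend and robust options, the deposited values, the minimum fold change, the detected-probe percentile and averaged probes left every count within 1.5 times. Where no cause is given below, the cause was not tested.

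Scaling and background changed counts of called probes as follows. Quantile normalization gave 3 at 24 h and 1511 in moribund vs 48 h. Median scaling gave 4 at 24 h and 39 at 48 h. Scaling within each read end gave 2349 in moribund vs 48 h and 9 lists at 48 h. Normexp gave 3 at 24 h, 23 at 48 h, 8122 at the moribund stage, 1 in 24 h vs 6 h and 9877 in moribund vs 48 h, with 1 list in 24 h vs 6 h and 3 in 48 h vs 24 h. The common floor gave 4 at 6 h, 2 at 24 h, 49 at 48 h, 589 at the moribund stage, 8 in 24 h vs 6 h, 28 in 48 h vs 24 h and 2182 in moribund vs 48 h, and it takes the order from dim values by its construction.

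No filter on dim probes, which tests more probes, gave 9507 at the moribund stage, 1 in 24 h vs 6 h and 14376 in moribund vs 48 h, with 15 lists at 6 h, 12 at 24 h, 17 at the moribund stage and 16 in moribund vs 48 h. The stricter filter gave 1 probe in 24 h vs 6 h, 4 lists in 48 h vs 24 h and 4 in moribund vs 48 h. Only the 2 groups compared, with fewer arrays in the estimate of the spread, gave 48 at 48 h, 20 in 48 h vs 24 h and 7756 in moribund vs 48 h.

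Slide as a block gave 3 probes at 24 h and 5 lists in 48 h vs 24 h. The same slide alone, with fewer arrays, gave 0 at 24 h, 394 at 48 h and 7229 in moribund vs 48 h, and could not be run for 48 h vs 24 h. Both use the 2 controls of a group's slide, so they are not separate checks. Scan session as a block gave 0 at 24 h, 0 at 48 h and 1746 at the moribund stage, with 2 lists at 6 h, 0 at 24 h and 3 at the moribund stage. The block and session 1 alone have only control 3, so they are not separate checks. Session 1 alone, with 1 control array assumed to vary like the other groups, gave 0 at 24 h, 0 at 48 h, 629 at the moribund stage and 7 in 48 h vs 24 h, with 2 lists at 6 h, 0 at 24 h and 3 at the moribund stage.

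The strand index as a covariate gave 3 at 24 h, 25 at 48 h, 903 at the moribund stage, 29 in 48 h vs 24 h and 65 in moribund vs 48 h, with 2 lists at 6 h, 3 at 24 h and 8 at 48 h. Without targets of 3' reads 1556 were called in moribund vs 48 h, with 2 lists at 6 h, 1 in 24 h vs 6 h and 4 in moribund vs 48 h. Without control 3 and 6 h 2 together 10275 were called at 6 h, 4966 at 24 h, 3683 at 48 h, 583 at the moribund stage, 1680 in 24 h vs 6 h, 27 in 48 h vs 24 h and 7360 in moribund vs 48 h, with 4 lists in 24 h vs 6 h.

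Camera with an estimated correlation called 0 lists in every comparison. Fry called 0 at 6 h, 24 h and 48 h, 2 at the moribund stage, 0 in 24 h vs 6 h and 48 h vs 24 h, and 4 in moribund vs 48 h. With 1 value per description, which tests fewer values, 3 lists were called at 6 h, 3 in 48 h vs 24 h and 2 in moribund vs 48 h.

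Reversed in direction were 2 named values in moribund vs control with normexp, GO080077 to -1.03 and the WSSV target to -0.20. The mitochondrial list reversed at 6 h with scan session as a block (adjusted p = 1.24e-07), in session 1 alone (3.11e-07), with scaling within each read end (0.405), with the strand covariate (0.914) and without 3' reads (0.617), at 48 h with the scan block (0.000931) and in session 1 alone (0.0013), and in 48 h vs 24 h with slide as a block (0.398). Cuticle reversed at 6 h in session 1 alone (0.759) and at 24 h with the scan block (0.672) and in session 1 alone (0.613), hepatopancreas markers at 24 h with the strand covariate (0.931), and haemocyanin in moribund vs 48 h with the strand covariate (0.96). The reversals with the scan block and in session 1 alone rest on control 3 as the only control.

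Leaving out each array in turn gave 0 to 7842 probes at 6 h, 3 to 1172 at 24 h, 19 to 893 at 48 h, 165 to 772 at the moribund stage, 0 to 6 in 24 h vs 6 h, 0 to 17 in 48 h vs 24 h and 0 to 5553 in moribund vs 48 h. Lists ranged from 4 to 11, 3 to 7, 4 to 7, 7 to 11, 1 to 4, 3 to 9 and 6 to 9 in the same order.

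Over the whole design the replicate numbers were not taken to pair the arrays. The correlation of deviations exceeded 0.1 in 13 of 30 pairs of arrays with the same number (median -0.04, range -0.54 to 0.75), and 8 of 16 arrays correlated best with an array of their own number. In moribund vs 48 h every pair with the same number exceeded 0.1 (0.387, 0.356 and 0.138), as in 48 h vs 6 h (0.734, 0.746 and 0.248), while in 24 h vs 6 h all 3 were negative, so a pairing of those groups is left open. With the replicate block limma called 0 probes at 6 h, 4 at 24 h, 44 at 48 h, 422 at the moribund stage, 0 in 24 h vs 6 h, 9 in 48 h vs 24 h and 3760 in moribund vs 48 h, and 4 lists at 6 h.

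Signal over background limits the folds, as 33.7% to 54.0% of probes per array were well above background. Values of probes with 0 arrays well above background in a group are bounds under each array's own floor. They hold for the scaling and background subtraction used here, and other settings gave smaller changes for some of them.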

Other observations

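The tests behind the hypothesis given here were chosen only after the result was seen.

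A principal component analysis of the kept probes put 57.3% of the variance on its first component, whose absolute correlation with the strand index was 0.95 over the 16 arrays. A candidate explanation is that arrays differ in how much labelled product of the opposite strand they carry, from the labelling or from antisense transcripts. With the strand index in the fit, 65 probes were called in moribund vs 48 h, against 3598 without it, but 903 in moribund vs control, against 380, so it removes calls in the former and adds calls in the latter. The index is computed from the same arrays and rests mostly on 5' reads, themselves of mixed strand, and the test does not tell labelling from biology. Nor does it tell strand from array brightness, as the index also sets dim against bright probes. The 75th percentile was 4.71 on 6 h 1 and 4.72 on 48 h 1, with indices of -2.33 and -2.23. It was 7.95 to 8.75 on the moribund arrays, with -4.54 to -4.32. Control 1, 2 and 4, at 5.43 to 6.02, had -4.55 to -4.25, and 24 h 3, at 4.74, had -3.12.

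Across probes, control 3 correlated at 0.95 to 0.96 with 24 h 1, 24 h 2 and 48 h 3 and at 0.81 to 0.88 with the other controls, but at 0.74 to 0.81 with the moribund arrays of its own scan session. Array 6 h 2 correlated more with control 2 (0.97) than with 6 h 1 (0.75) and 6 h 3 (0.72). The median log2 signal of 12 ERCC control probes, of which 1 or 2 were well above background per array, was 0.304 to 0.344 on control 1, 2 and 4 and 0.88 to 1.40 on the arrays of session 1, control 3 included (1.16).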
